A study of Mus musculus with 2 samples.

How the data were processed

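The series describes Paired-Damage on nuclei of mouse frontal cortex, with 1 DNA damage library and 1 RNA library of the same nuclei. Only the DNA damage library had values to work from. The labels give the animals as male C57BL/6J mice of 8 weeks and 11 months, and do not say which barcode came from which animal, so all nuclei were treated as 1 group and age was not used.

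The authors deposited 1 table of aligned stretches of DNA for the DNA damage library, with chromosome, start, end, barcode, read count and strand, and the count in each line is the number of reads behind it. Per the submitters' processing notes, reads were trimmed with cutadapt and handled with SAMtools, with builds hg38 and mm10 named and no versions or settings. Chromosome names and coordinates fit mm10. The aligner and the removal of duplicates are not given in the sources used here. The table was not filtered by barcode. The read count was 1 in 99.7% of lines and at most 7. Lines were 20 to 157 bases long, with 28.6% at exactly 150 bases, while the labels give a first read of 100 bases. The cause of that difference is not stated. The meaning of the parts of the barcode is not stated either, so they were never used as groups of animals.

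Each line was counted once, as 1 fragment, at its midpoint. A barcode with at least 1000 fragments on chromosomes 1 to 19, X and Y was taken as a nucleus. No doublet caller was run, and no nuclei were removed for high depth. No barcode was removed for any other reason. The deepest nucleus had 169655 fragments. Only bases in 10 kb bins with at least 1 fragment counted as covered. Lines on unplaced contigs were left out of every density.

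Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10. After genes placed on patches and scaffolds were left out, it held 49603 genes, of which 21779 are protein-coding. The table has no strand, exon, UTR or sequence. For that reason promoter enrichment by transcription start site, the CpG classes of promoters, exon, intron and UTR densities, the relation with GC content and every GC correction were planned and not run. Random gene lists were matched on length and not on GC. Density around both ends of genes stood in for promoters, and gene bodies lost 2 kb at both ends in place of the first 2 kb.

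Gene-body density was set against intergenic sequence outside every annotated gene, on autosomes. Chromosome densities were set against the autosomal mean. Ratios have 95% intervals from Poisson counting error, and the mitochondrial share has an exact Clopper-Pearson interval. Reads from 1 molecule are not independent, so the true error is wider than these intervals. The 23 gene lists were fixed before the data were examined, as were the main measures, the nucleus minimum, the Leiden resolution and the first set of alternatives. Lists covered markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, and fibroblast and meningeal cells. The others were housekeeping, immediate early, both repair lists, antioxidant defence, respiratory chain, long neuronal and fragile-site, Hox, liver, keratin, olfactory receptor, vomeronasal receptor, ribosomal protein, clustered protocadherin and histone genes. The universe was 20002 protein-coding genes of at least 1 kb on autosomes and X, with X genes scaled by the X to autosome ratio. Each list's median was placed among 10000 random lists, each drawing for every member 1 of the 100 genes nearest in length. No p-values were computed, because genes and nuclei of 1 library are not replicates.

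The genes named are those set by a rule written before the data were examined. The rule takes the 2 highest and 2 lowest members of each list, of which the text names some. It takes the 10 highest and 10 lowest of all protein-coding autosomal genes of at least 5 kb, without model genes and genes in a bin over 10 times the median. It takes the 5 genes with the largest ratio in each direction between clusters, and Ogg1, Parp1, Xrcc1 and Apex1 in any case. Model genes were those with a symbol of Gm and digits or ending in Rik. Those left out numbered 812, and 1 gene lay in a bin over 10 times the median. 1700049E17Rik1 stayed in the ranking, because its symbol does not end in Rik.

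Nuclei were clustered on presence or absence of fragments in 50 kb bins of odd-numbered autosomes, using bins seen in at least 100 nuclei. Values were weighted by term frequency and inverse document frequency and reduced by truncated singular value decomposition. The first component was dropped because it followed depth, with a Spearman rho of 0.992 across nuclei. Components 2 to 30 entered a graph of 15 nearest neighbours, which was split by the Leiden method at resolution 0.5. Differences between clusters were read on even-numbered autosomes, for genes and 1 Mb bins with at least 200 fragments in both clusters. The numbers of components and neighbours were not fixed beforehand and were settled after cluster results under other numbers had been seen.

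Alternatives set beforehand weighted lines by read count, took all barcodes, took at most 1000 fragments of each nucleus, took lines under 150 bases, left out extreme bins, placed fragments by their start, trimmed gene ends, left lists unmatched, raised the gene length minimum, moved the nucleus minimum, and changed the chromosomes, resolution, bin size and nucleus minimum of the clustering. Alternatives added after seeing the data collapsed identical lines of a nucleus, merged lines of a nucleus within 1 kb, set genes against their 50 kb flanks, read lists at gene ends, and changed the components and bins of the clustering. The list and cluster steps were tested on simulated data first. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, pyarrow 21.0.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.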

Results

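Frontal cortex from C57BL/6J males supplied the nuclei profiled with Paired-Damage, a single-nucleus assay that marks oxidative lesions of DNA with biotin and cuts adapters in beside them with Tn5 transposase bound to protein A. The lesions marked are oxidised guanine, abasic sites and single-strand breaks, and RNA is barcoded in the same nuclei. The labels describe 1 DNA damage library and 1 RNA library, and the values here come from the DNA damage library. The RNA library was not analysed here. The protocol names mice of 8 weeks and of 11 months, but the labels tie no barcode to an animal or an age, so the ages were not compared. With 1 library there were no replicates, and all intervals given cover counting error only. No library without the labelling step was available, so a density below is the sum of labelled damage and of any background insertion by the transposase.

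The library held 171326919 fragments, each an aligned stretch of DNA carrying 1 barcode, spread over 4926291 barcodes. A single fragment was all that 28.9% of the barcodes carried. The 54387 barcodes with at least 1000 fragments on chromosomes 1 to 19, X and Y are called nuclei here, and they held 71.5% of the fragments on those chromosomes. The median nucleus had 1766 fragments, with quartiles of 1335 and 2506. In total the nuclei gave 122433619 fragments on those chromosomes. Of these, 118528679 lay on autosomes, or 49.6 per kb of covered autosomal sequence. Densities below are fragments per covered base divided by the autosomal mean, unless another base is named.

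The first comparison asked whether damage fragments were spread evenly between genes and the sequence outside them. Protein-coding gene bodies carried slightly more fragments than intergenic sequence. The density in gene bodies was 1.133 times the intergenic density, with a 95% counting interval of 1.1326 to 1.1335. Gene bodies held 52240494 fragments on 979386295 covered bases, and intergenic sequence held 56844831 fragments on 1207499084 covered bases. Relative to the autosomal mean, gene bodies stood at 1.08 and intergenic sequence at 0.949. Without the outer 2 kb at both ends, gene bodies stood at 1.138 times intergenic sequence, so the excess did not come from gene ends. Bins of 10 kb counted as covered with 1 fragment, so sequence where reads cannot be placed stayed in the covered bases. Leaving out bins more than 10 times above or below the median bin raised the intergenic density from 47.1 to 47.8 per kb. The ratio of gene bodies to intergenic sequence was then 1.125, so such bins accounted for only part of the excess. The effect of unplaceable sequence within the bins kept was not tested. Across 2381 autosomal 1 Mb bins, the share of gene sequence and density were nearly unrelated (Spearman rho 0.092).

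Long genes carried more fragments per base than short ones. Among 10 groups of genes ranked by length, the shortest group, with a median length of 2.04 kb, had a median density of 0.912. The longest group, with a median length of 198 kb, had a median density of 1.11. Relative to the 50 kb on both sides of each gene, the same groups stood at 0.995 and 1.08, so the range narrowed when each gene was set against its surroundings. Transcripts, and so expression, were not measured in the data used here.

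**Figure D1:**
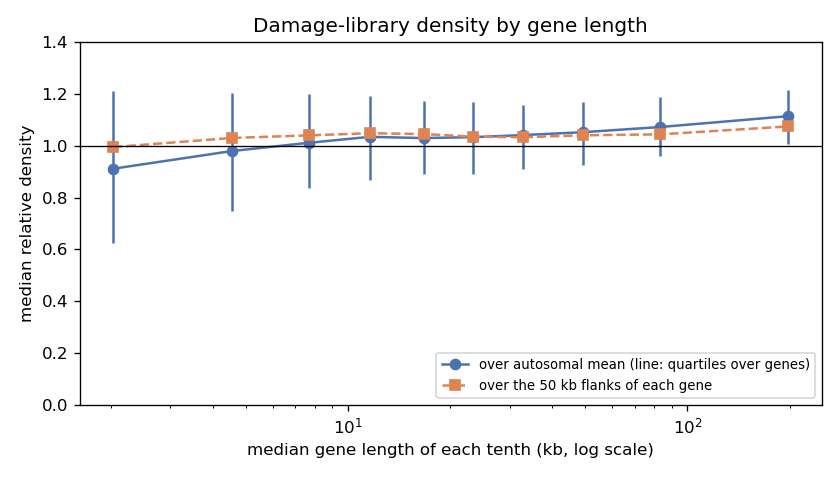
Median fragment density of protein-coding genes in 10 groups ranked by gene length (x axis, kb, log scale), over the autosomal mean (circles, with quartiles over genes as vertical lines) and over the 50 kb flanks of each gene (squares). Over the autosomal mean the medians run from 0.912 in the shortest group to 1.11 in the longest.

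Promoters could not be placed, because the gene table gives no strand. Both ends of each protein-coding gene of at least 5 kb were read together in their place, a choice made after the data were seen. Gene ends showed a small, narrow dip with a small rise just outside it. Within 1 kb either side of the ends of 16048 genes, the density was 1.087 times the intergenic density, with an interval of 1.0856 to 1.0880. In steps of 100 bases out to 5 kb on either side, the lowest density was 0.962 of the autosomal mean, in the first step inside the gene. The highest was 1.09, in the second step outside it.

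**Figure D2:**
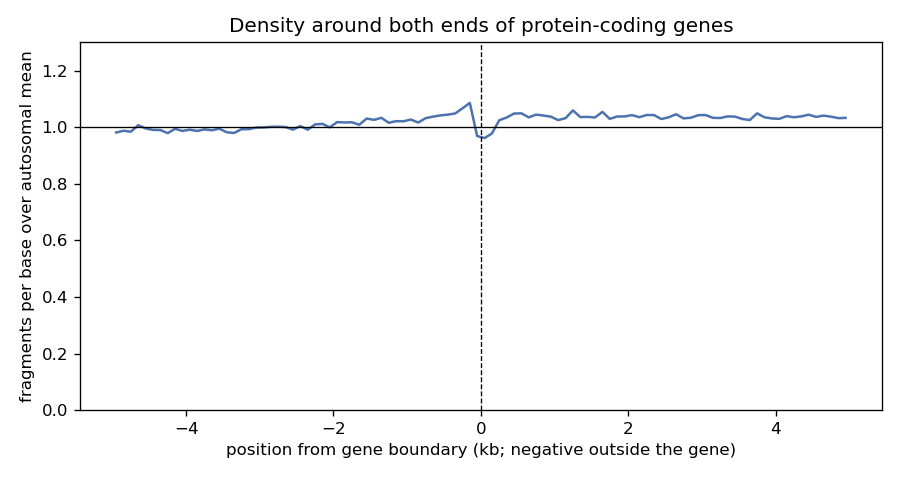
Fragment density over the autosomal mean (y axis) in steps of 100 bases around both ends of 16048 protein-coding genes (x axis, kb, negative values outside the gene). The line stays between 0.962 and 1.09, with its lowest and highest points close together at the gene end.

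The second comparison set the chromosomes against each other. In male mice X is present in 1 copy against 2 of each autosome. The X chromosome carried 0.485 times the autosomal density, with an interval of 0.4850 to 0.4859, close to the ratio of copy numbers. Per copy, X stood at 0.971 of an autosome, and at 1.05 when bins with extremely high or low density were left out, inside the range of the autosomes both times. With all bins that range ran from 0.829 on chromosome 7 to 1.08 on chromosome 3. Chromosome 17 stood at 0.923, chromosome 19 at 0.942, chromosome 18 at 1.07 and chromosome 10 at 1.06. The Y chromosome stood at 0.0322, and at 0.284 without extreme bins, which left 3440000 of its 50900000 covered bases. The Y value thus rests on the bins used.

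**Figure D3:**
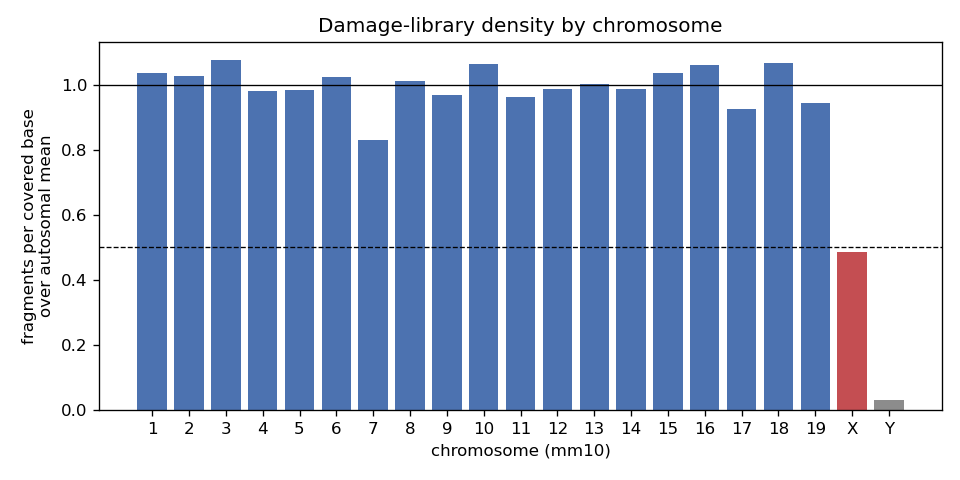
Fragments per covered base of each chromosome over the autosomal mean (bars). The solid line marks 1 and the dashed line the ratio that 1 copy against 2 gives; X stands at 0.485, and chromosomes 7 and 3 are the lowest and highest autosomes at 0.829 and 1.08.

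The mitochondrial genome gave few fragments. It held 2573 of the fragments of the nuclei, or 0.00210% (exact binomial interval 0.00202% to 0.00218%). At least 1 such fragment was seen in 1752 nuclei, which is 3.22% of them, and the median nucleus had 0. The assay starts from isolated nuclei, so this share describes what remained with the nuclei. The share is not a density per base, so it cannot be set beside the chromosome densities.

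The third comparison asked whether groups of genes with a shared role or cell type stood apart from genes of like length. The long neuronal and fragile-site genes, with Cadm2 and Dmd at the top of the list, were denser than length-matched genes. The Hox clusters, skin keratins, vomeronasal receptors and clustered protocadherins were sparser in the main setting. The protocadherins lay above their range in 3 of 14 alternatives. The other 18 of the 23 gene lists, among them all 8 lists of cell-type markers and both repair lists, lay inside the range of random lists. Of those 10 lists, the astrocyte markers and the nucleotide excision and double-strand break repair genes left the range under some alternatives, in 1 and 2 of 14. Each list was placed by its median among 10000 random lists of the same size and matched on gene length, with the central 95% as the range. Random lists drew genes from across the genome, while genes of a family can be neighbours with a shared local density. Pcdhgc5, for one, lies inside Pcdhgc3, so both count the same fragments. The range may thus be too narrow for the Hox, keratin, receptor and protocadherin lists.

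The long neuronal and fragile-site list had a median of 1.23, against 1.080 to 1.203 in random lists, at percentile 99.9. Within it Cadm2, at 16:66655416-67620917, stood at 1.42 with 67780 fragments, and Dmd at 1.33 once scaled to the X density, while Wwox was the lowest at 0.945. Relative to their own 50 kb flanks, these genes lay inside the random range. The Hox list had a median of 0.718, against 0.859 to 1.11 in random lists. Hoxb1 was its lowest member at 0.305 and Hoxd11 its highest at 1.09, and this list too lay inside the range relative to flanks. The skin keratins had a median of 0.805 against a lower bound of 0.847, with Krt16 lowest at 0.452 and Krt77 highest at 1.21, and lay inside the range in 3 of 14 alternatives, relative to flanks or without gene ends.

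The vomeronasal receptors had a median of 0.440 and the clustered protocadherins one of 0.864, against lower bounds of 0.982 and 0.996. Whether reads were shared among members of a family was not tested, so their densities are uncertain. The protocadherins lay below their range in 9 of 14 alternatives, above in the 3 that used flanks or gene ends, and inside in the 2 that trimmed gene bodies or left out short genes. The olfactory receptors, with 325 of 1109 genes used, stood at 0.852, inside their range. They kept that place in only 8 of 14 alternatives, lying above relative to flanks and below in the others.

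**Figure D4:**
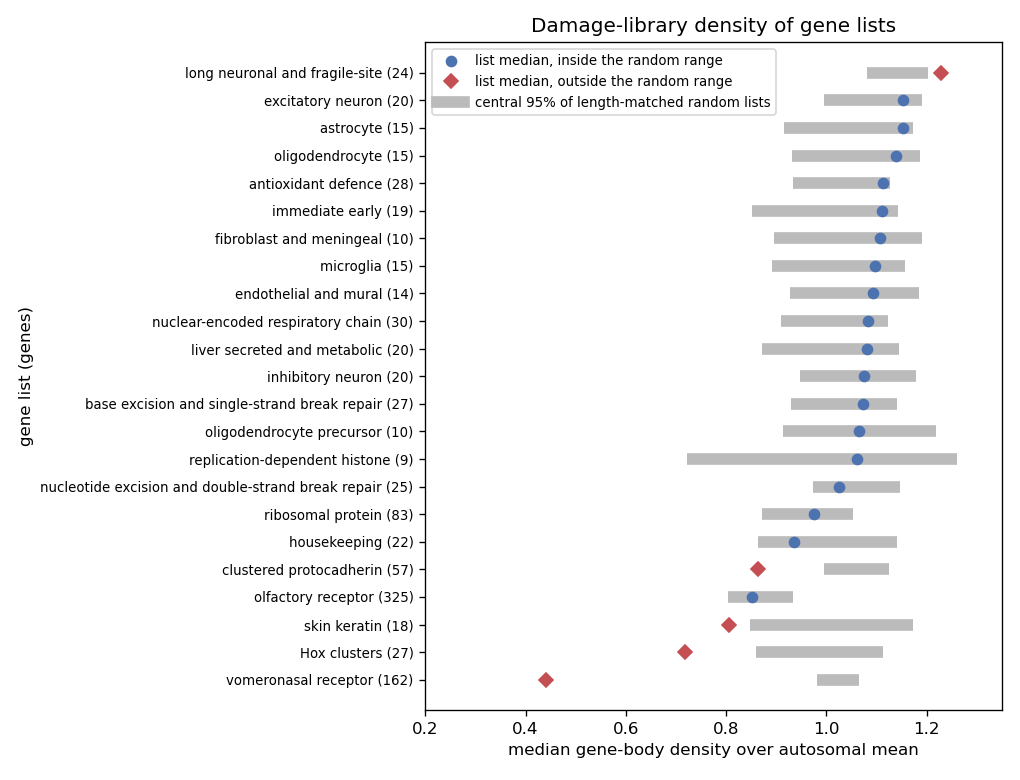
Median gene-body density over the autosomal mean of 23 gene lists (points, with the number of genes beside each name) and the central 95% of 10000 length-matched random lists of the same size (grey bars). Red diamonds mark the 5 medians outside their bars, from 0.440 for vomeronasal receptors to 1.23 for long neuronal and fragile-site genes.

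Among cell-type lists the excitatory neuron, astrocyte and oligodendrocyte markers had medians of 1.15, 1.15 and 1.14. The inhibitory neuron markers stood at 1.08, the oligodendrocyte precursor markers at 1.06, the microglia markers at 1.098, the endothelial and mural markers at 1.09, and the fibroblast and meningeal markers at 1.11. Of these, the astrocyte markers came closest to the bound, at percentile 94.6. The immediate early genes stood at 1.11 and the antioxidant defence genes at 1.11, at percentiles 93.3 and 95.5. The base excision and single-strand break repair genes stood at 1.07, and the nucleotide excision and double-strand break repair genes at 1.03. The nuclear-encoded respiratory chain genes stood at 1.08, the housekeeping genes at 0.936, the ribosomal protein genes at 0.974, the histone genes at 1.06, and the liver secreted and metabolic genes at 1.08. The histone list was meant for replication-dependent histones, but 9 of its 67 members were used, among them H1f0 and H1f10, which are not of that kind. The list step was tested on simulated counts drawn from gene length, with the same spread for all genes and every gene independent. In them, 5 of 6 lists with known changes were recovered and 1 of 17 unchanged lists fell outside the range. Observed median densities rose with length and scattered unequally between lengths, so these rates need not hold for the real lists. The 1 list multiplied by 0.9 was missed and the 1 list multiplied by 1.1 was recovered.

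The 4 genes of oxidative base and strand break repair chosen beforehand were read in any case. Ogg1, at 6:113326972-113334877, stood at 1.79 (interval 1.66 to 1.93) with 703 fragments from 584 nuclei. Apex1 stood at 1.49 (1.28 to 1.74), Parp1 at 1.08 (1.03 to 1.13) and Xrcc1 at 1.06 (1.00 to 1.11). One stretch of 200 bases held 20.6% of the fragments of Ogg1 and 17.5% of those of Apex1. In the length group with a median of 7.67 kb, the quartiles of density were 0.837 and 1.199, so Ogg1 lay above the upper one. With nearly empty genes included, densities scattered more among genes as short as Ogg1 than among long genes. The SD of log2 density was 0.63 at 5 to 10 kb, 0.68 at 10 to 30 kb and 0.23 over 100 kb. Apex1 is shorter than the genes in those classes. In the immediate early list Arc and Fos were highest at 1.85 and 1.68, and Egr3 and Junb were lowest at 0.746 and 0.756. In the antioxidant list Hmox1 was highest at 1.93 and Prdx2 lowest at 0.645. Atp5a1 was the highest respiratory chain gene at 1.85.

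Over all 15185 protein-coding autosomal genes of at least 5 kb that were ranked, most lay near the mean. Densities above 1.5 times the mean were found for 290 of them and densities below 0.5 for 461. The highest were Cyp4a14 at 9.21 times the mean, Klrk1 at 4.27, Hjurp at 3.73, Mroh2a at 3.63, Ugt1a1 at 3.10, Tshb at 2.65, Mitd1 at 2.58, B9d2 at 2.23, S100a11 at 2.21 and Fhdc1 at 2.20. In Klrk1, Cyp4a14, Tshb and Mitd1, one stretch of 200 bases held 77.0%, 69.5%, 66.8% and 52.8% of the fragments, so their values rest largely on that stretch. The lowest were Vmn1r63, Vmn2r47, Cphx2, 1700049E17Rik1, Entpd4b, Smok3b, Ccl21b, Pramel44, Pramel40 and Amy2a2, each with 2 fragments or fewer. Whether reads were shared with similar genes was not tested, so their low values are uncertain.

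The last comparison asked whether nuclei fell into groups with different damage maps. They fell into 2 clusters whose maps differed little on chromosomes that had not defined them. But the number of clusters ran from 1 to 8 with the settings, and the difference grew under some of them. Of the 8 clusters, found at resolution 1.0, the smallest held 5, 5 and 3 nuclei. Nuclei were grouped on odd-numbered autosomes and read on even-numbered ones, giving clusters of 45245 and 9142 nuclei. Across the values of the last barcode part, whose meaning is not stated, the larger cluster held 81.1% to 86.8% of nuclei. Metap2, Sec22a, Slc26a4, Fam78a and Pak6 had the largest ratios of cluster 1 to cluster 2, from 1.21 to 1.28. Sem1, Cep170b, Nup35, Ankrd24 and Erlin2 had the smallest, from 0.757 to 0.799. These are the extremes of 3742 genes and have no test behind them, and none of them was among the extremes in the 4 other settings that read the same chromosomes and gave more than 1 cluster.

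Over 1158 held-out stretches of 1 Mb, the SD of the log2 ratio between the clusters was 0.027, against 0.020 from counting alone. At resolution 1.0 it was 4.56 times the counting value between the 2 largest clusters, and with repeat-like bins and component 2 left out 3.33 times. Counting alone takes every fragment as independent. Fragments of a nucleus within 1 kb of each other raise that expectation by a factor of 1.16, so part of the difference is accounted for. Grouping on the even-numbered autosomes gave a different partition, with an adjusted Rand index of 0.0055 between the groupings, where 0 is the value for unrelated groupings. Median log2 differences of the cell-type marker lists on the held-out chromosomes lay between -0.04 for fibroblast and meningeal genes and 0.06 for endothelial and mural genes (cluster 1 over cluster 2), so the clusters carry numbers and no cell type. In simulated nuclei, groups differing 1.5-fold in some of the 1 Mb stretches were recovered with an adjusted Rand index of 0.86, and groups differing 1.2-fold were not found. These simulations held 6000 nuclei, fewer than the data, so they set no detection limit for this library.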

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

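No test was run on the signals in this part, which were described after they were seen. Barcodes with fewer than 1000 fragments on chromosomes 1 to 19, X and Y carried 48801280 fragments, 28.5% of all fragments on those chromosomes, and entered only the alternatives that lowered or dropped this minimum. They numbered 4871904. Their fragments had a gene-body to intergenic ratio of 1.143 and an X to autosome ratio of 0.483, against 1.133 and 0.485 in the nuclei. Damaged nuclei, free DNA and barcode errors were not told apart, and no biological explanation was tested.

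Unplaced contigs held 88445 fragments, 0.0516% of the library, in 39 contigs. The contig with most held 35.8% of them. Gene positions on them were not used here, and they were left out of the densities.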

How the results depend on the processing

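Settings that merged or collapsed lines, used flanks or gene ends, or changed the components of the clustering were chosen after the data were seen. The excess in gene bodies stayed above 1 under all 9 alternatives, between 1.123 and 1.140. It was 1.136 with all barcodes, 1.130 with at most 1000 fragments per nucleus, 1.140 for lines under 150 bases, 1.125 without extreme bins, 1.132 with identical lines collapsed, 1.123 with lines within 1 kb merged, and 1.138 without 2 kb at both ends. Gene-end density was 1.098, 1.089, 1.103, 1.083 and 1.066 under all barcodes, at most 1000 fragments, lines under 150 bases, collapsed and merged lines, and 1.081 within 500 bases.

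The X to autosome ratio was 0.4847 with all barcodes, 0.4798 for lines under 150 bases, 0.4917 with lines merged, and 0.5242 without extreme bins, which leaves out nearly empty bins of X. The mitochondrial share was 0.00169% with at most 1000 fragments per nucleus, 0.00221% for lines under 150 bases and 0.002001% with lines merged. For all but the change of bins the cause was not tested. The median nucleus had 1452 fragments at a minimum of 500 and 2752 at a minimum of 2000, by construction.

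Between 5 and 7 gene lists lay outside the random range under the 14 alternatives, but membership moved. Vomeronasal receptors lay below in all 14. Long neuronal genes lay above, and Hox genes below, in 12 of 14, and both lay inside relative to flanks. Keratins lay below in 11 and protocadherins in 9, with 3 above. Housekeeping genes lay above without gene ends, at 1.201, and below relative to flanks, at 0.886. The immediate early genes lay above without gene ends, at 1.21, and the antioxidant list with at most 1000 fragments per nucleus, at 1.16. Astrocyte markers lay above for lines under 150 bases, at 1.18. The nucleotide excision and double-strand break repair genes lay below relative to flanks, at 0.955. Olfactory receptors stayed inside in 8 of 14. The cause was not tested.

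The SD between clusters (and its ratio to counting) was 0.0299 (1.94) when clustering on even-numbered autosomes, 0.0875 (4.56) at resolution 1.0, 0.0283 (1.33) with 20 kb bins, 0.0291 (1.46) with components up to 15, 0.0560 (3.33) with repeat-like bins and component 2 left out, and 0.0345 (2.33) for the even-numbered version of that. Resolution 0.25 and a minimum of 2000 fragments gave 1 cluster and so no value. The clusters depended on these choices, and the cause was not tested. Membership also varied with the last barcode part. Over its values, cluster 1 held 81.1% to 86.8% of nuclei in the main setting, and 53.0% to 66.3% when clustering on even-numbered autosomes. At resolution 1.0 cluster 1 held 24.6% to 36.8%. The cause of that was not tested either.

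Of 112 named genes, none with an interval wholly on 1 side of the mean crossed it under 4 alternatives. With intervals that held the mean, Hoxd11 fell to 0.899 with lines under 150 bases and Krt72 to 0.908 with at most 1000 fragments per nucleus. Hoxb1, at 0.305, fell to 0.199 in the latter. With lines under 150 bases, 30 left their interval, 15 upward and 15 downward. With lines merged 5 did. The promoter results, the GC relation and all GC corrections were not run for want of strand and sequence. No paired analysis was run, because only the DNA damage library had values to work from. What depth limits was not simulated.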

Other observations

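Of the tests in this part, those of merged fragments, of lone fragments, of fragments of 150 bases and of the relation between ratios over barcode parts were chosen after the results were seen. The tests without the densest 200 bases and within a band of depth were set before their values were seen, except that the first quartile used in the former was chosen afterwards, when the median fell between the bounds set.

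One region stood out after its values were seen. A stretch of 100 kb on chromosome 1, at 1:88210001-88310000, held 15567 fragments, which per 10 kb is 3.07 times the median bin. It was the only autosomal run of at least 5 neighbouring bins above 2 times that median. Ugt1a1, Mroh2a and Hjurp lie wholly inside it. It also overlaps other Ugt1a genes, and ends inside Trpm8. No narrow pile-up made it, since the densest 200 bases of Hjurp, Mroh2a and Ugt1a1 held 3.31%, 2.99% and 6.23% of their fragments. A difference in copy number from the reference, a collapsed repeat and a local excess of damage were not told apart.

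Gene content of the surroundings was nearly unrelated to fragment density. Across 2381 autosomal 1 Mb bins, which are not independent replicates, the Spearman rho between the share of bases in protein-coding genes and density was 0.092. The fifth of bins with the least gene sequence had a median density of 1.02 and the fifth with the most had 1.04. The densest single 10 kb bin, at 2:98660001-98670000, held 51575 fragments, 102 times the median bin. The 6 bins above 10 times the median held 0.0787% of autosomal fragments.

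Genes with a density above 1.5 times the autosomal mean numbered 290, and their median length was 11.2 kb against 26.8 kb for all genes ranked. Near-repeat fragments of single nuclei are argued against as the whole cause, since 79.3% of the 290 genes stayed above 1.5 once fragments of a nucleus within 1 kb were merged. A single narrow stretch in each gene was tested next: without the densest 200 bases the median fell from 1.61 to 1.48, with a first quartile of 1.41, and 119 of the 290 genes stayed above 1.5. Over all genes ranked, the same step lowered the median from 1.05 to 1.02. The median of the 290 genes lay between the bounds set beforehand, and 14 of them fell to the level such a cause needs. It is thus argued against only as the whole cause. A bias from base composition stays open, as does a local excess of damage, and neither was tested because no sequence was used.

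More fragments lay on the plus strand, 54.5%, than on the minus strand. Copies of 1 molecule, if counted as separate fragments, are a candidate cause. Among fragments with no other fragment of the nucleus within 1 kb the plus-strand share was 51.1%, and among the others 64.2%. Fragments without such a neighbour made up 74.0% of the total. When positions were dealt at random to nuclei, 0.424% had such a neighbour. Line length is a further candidate, since lines of 150 bases had 50.4% on the plus strand and shorter lines 56.4%. The excess lay mostly where both held: 71.3% among shorter lines with such a neighbour, 51.7% among shorter lines without one, and 51.9% among lines of 150 bases with one. How either would favour a strand was not tested, and no biological explanation was tested.

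Gene-body enrichment differed between parts of the library. Over the 39 values of the first barcode part, the ratio of gene bodies to other autosomal sequence ran from 1.104 to 1.177, with counting half-widths of at most 0.0039. The ratio fell with the median depth of the parts (Spearman rho -0.73). Depth is argued against as the whole cause, because among nuclei of 1500 to 2000 fragments the range was 0.0807, with counting half-widths of at most 0.0080, against 0.0730 over all nuclei. A bias that acts on whole regions could lie behind it: the X to autosome ratio moved the other way, with a Spearman rho of -0.92 over the 39 values, which are parts of 1 library and not replicates. Differences between animals or ages stay open and untested, since the labels do not say what the barcode parts stand for.

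The 6 values of the last barcode part held 6185 to 12720 nuclei, with medians of 1428 to 2159.5 fragments per nucleus. Their ratio of gene bodies to other sequence ran from 1.11 to 1.17.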
